A study of Mus musculus with 6 samples.

How the data were processed

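RNA sequencing was measured in 6 samples of vascular smooth muscle cells, the contractile cells of the artery wall, grown from mouse aorta. Of these, 3 had been treated with a small interfering RNA against Sirt6 (siSirt6) and 3 were controls (Control), all for 48 h. Sirt6 encodes an NAD-dependent deacylase of the sirtuin family. Per the labels' protocols, total RNA was taken up in Trizol and libraries were made with a stranded mRNA kit. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and the mouse build mm10, without versions, roles or order. What the control cultures received in place of the siRNA is not given in the sources used here.

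Each deposited table holds 1 library and gives a signal per gene for the same 7384 genes. The deposited signal values were whole reads divided by one factor per library: 100% of them in every library came out whole, within 0.001 reads, when divided by the smallest step between values. The factors that the steps give were 1.0248, 1.0271 and 1.0354 for Control replicates 1 to 3 and 1.0113, 0.9701 and 0.9609 for siSirt6 replicates 1 to 3. How the authors obtained the factors is not given in the sources used here. The values are called normalised read counts in the text. The tables appear to be a selection of differing genes: their rows were ordered by strength of difference (Spearman rho 0.988 between row order and the limma p, across genes), and 13 of the 7179 genes tested had an unadjusted limma p of 0.05 or more. No column was left without a sample. Genes outside the tables were not analysed here, so enrichment against the whole transcriptome was not tested.

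The design fixed before the data were examined assumed counts and edgeR, and named limma for values that turned out not to be counts. The main test was therefore limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, 2-sided) on log2(value + 1), comparing 3 siSirt6 with 3 Control libraries with no other term. Log2 fold changes and their errors are on this log2(value + 1) scale, which understates the change of low genes. Changes given as N-fold, or as a part of the Control level, are ratios of the group means of the deposited values. Genes with a value of at least 10 in at least 3 libraries were tested; 205 of the 7384 were left out. Benjamini-Hochberg adjustment ran over the 7179 tested genes with a threshold of 0.05. Since the tables hold a selected part of the transcriptome, a stricter adjustment is given as well, over all 55536 annotated genes with every gene outside the tables taken as p of 1. Symbols were taken from the tables. Positions, biotypes, transcript lengths and GC content came from GENCODE vM21 on GRCm38, the build also called mm10, in which 7332 of the 7384 identifiers were found; 7331 had a length and GC content.

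Gene groups were 33 lists fixed before the data were examined: the sirtuin family, contractile smooth muscle, extracellular matrix of synthetic smooth muscle, matrix proteases and inhibitors, osteochondrogenic and calcification genes, glycolysis, hypoxia response, oxidative phosphorylation, fatty acid oxidation and PPAR, cholesterol synthesis and SREBP2, NF-kB and inflammatory genes, type I interferon response, senescence-associated secreted factors, p53 targets, cell cycle G1/S and S phase, cell cycle G2/M, DNA repair and telomere, ribosomal proteins, ribosome biogenesis and MYC, NRF2 antioxidant, ER protein folding stress, ATF4 amino acid response, TGF-beta response, YAP and TEAD targets, immediate early genes, Notch, lysosome and autophagy, circadian clock, and markers of endothelial cells, of macrophages and leukocytes, of adventitial fibroblasts, of adipocytes, and of Schwann cells and neurons. The 32 lists with at least 3 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, against the other listed genes, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 libraries in place of the number of genes. Fry asks whether a list's own genes differ, without reference to other genes. The genes named are Sirt6, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 CPM of listed values and group ranges that did not overlap, leaving out symbols of unnamed or predicted genes, and from each list the 4 members with the smallest p; some of these are not reported here. Other genes named were chosen after their values were seen and are said to be so.

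The listed genes took 14458847, 14469651 and 14563794 reads in Control replicates 1 to 3 and 15526399, 14866718 and 14614192 in siSirt6 replicates 1 to 3. The whole library depth is unknown. Count tests were run on the recovered reads of 5 libraries as alternatives; siSirt6 replicate 1 was left out of them by an automatic check of the unit that did not accept its step of 0.988823, although its values came out whole like those of the other libraries. Those alternatives were edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom. Other alternatives were other scalings over the listed genes, other filters, pseudocounts of 0.5 and 5, robust variance turned off, the replicate number as a block, each library left out in turn, and removal of each library's trend on transcript length and GC content by natural splines with 5 degrees of freedom. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 1.94 and 2.495 over their recovered reads, so none looked like a repeated deposit of another. That does not show that they came from separate cultures. The biological coefficient of variation was 2.74% (edgeR, 5 libraries). This value, and the standard errors given, rest on genes that appear to be selected for differing between the groups, which may lower them. The labels do not say that the 3 samples of a group came from different animals, so p-values measure the spread between these samples.

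The tests were tested on simulated data drawn from the means of the 7179 tested genes, with 200 genes changed between siSirt6 and Control. There limma on 6 libraries called 69% of the genes changed 1.2-fold and 97% of those changed 1.5-fold, with 8 unchanged genes called. The edgeR test on 5 libraries called 64% and 96%, with 11 unchanged genes called. Of 200 random lists, 3.5% had a camera p under 0.05. Simulated genes were drawn independently and without selection. These rates therefore do not carry over to lists whose genes vary together, or to tables of selected genes. The estimated correlation of the ribosomal protein list, for example, was 0.446. A planted length trend gave 65.9% of unchanged genes a p under 0.05, and 4.95% after the trend was removed. That trend was planted on the same transcript lengths that the removal fits, without a GC effect, so the removal had to succeed. The check does not cover lengths that differ from those expressed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.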

Results

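Gene expression was compared between mouse aortic smooth muscle cells treated for 48 h with an siRNA against Sirt6 and control cultures, with 3 libraries per group. The study asked what the loss of Sirt6 changes in the transcriptome of these cells. Normalised read counts were given for 7384 genes, which took between 14458847 and 15526399 reads per library.

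Sirt6, on chromosome 10 at 81621785 to 81627797 (GRCm38, minus strand), stood at normalised read counts of 251.7, 257.0 and 270.4 in the Control libraries and 44.5, 59.8 and 63.5 in the siSirt6 libraries. It fell to 0.215 of its Control level, from 259.7 ± 9.62 to 55.9 ± 10.1 (SD, n = 3), a log2 fold change of -2.21 with a standard error of 0.141. Sirt2 was the other sirtuin tested and rose 1.14-fold (log2 0.18 ± 0.030 SE), a rise that was 0.00 once the trend on transcript length and GC content was removed. The remaining 5 sirtuins were not analysed here.

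In the siSirt6 cultures, genes of ribosomal proteins, ribosome biogenesis, glycolysis, the antioxidant response and the type I interferon response rose as groups, and genes of mitosis fell. These calls, and that of endothelial markers, came from camera with a preset correlation and were lost with an estimated one (adjusted p between 0.164 and 0.251 with an estimated correlation). Smooth muscle actin Acta2 rose 1.66-fold and the elastin cross-linking enzyme Loxl1 rose 1.86-fold, while the adhesion receptor Vcam1 fell to 0.427 of its Control level. Markers of endothelial cells rose as well, among them the VEGF receptor Kdr at 2.97-fold. Of the 7179 genes tested, 3624 were higher and 3542 lower in siSirt6, and 554 of them changed at least 2-fold, 288 upward and 266 downward; among genes with a mean of at least 5 CPM of listed values, 207 did.

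**Figure D1:**
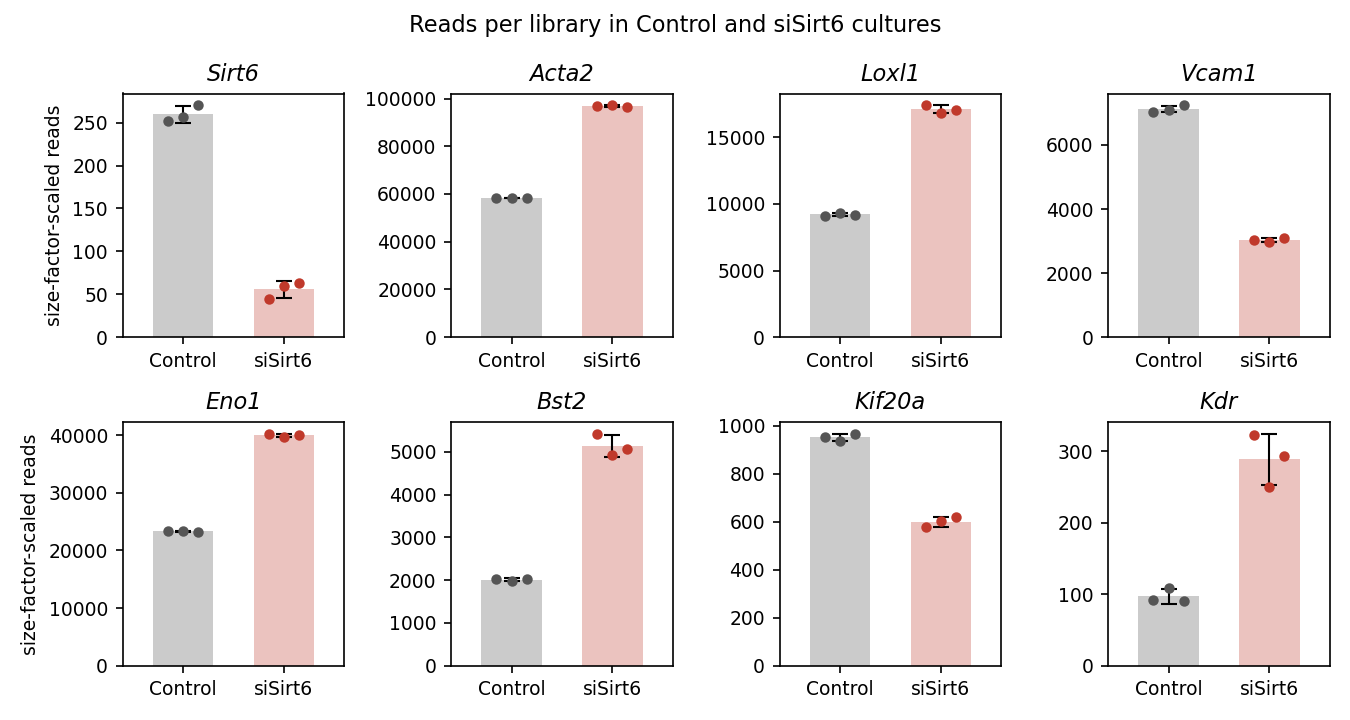
Normalised read counts (y axis, reads divided by the library's size factor) of 8 genes in the Control and siSirt6 groups (x axis); points are libraries, bars are means and whiskers SD (n = 3). Sirt6, Vcam1 and Kif20a lie lower in every siSirt6 library, and Acta2, Loxl1, Eno1, Bst2 and Kdr lie higher.

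Among the genes taken by the naming rule, Cxcl5, a chemokine that attracts neutrophils, rose from 17.5 ± 1.63 to 150.8 ± 19.9 (SD, n = 3), a log2 fold change of 3.03 with a standard error of 0.199. Vgf, the precursor of several neuropeptides, rose 6.70-fold, from 109.8 ± 10.3 to 735.4 ± 28.7. The non-classical MHC class I genes H2-M1 and H2-M9, neighbours on chromosome 17 (36670008 to 36672219 and 36639285 to 36642666), rose 6.79-fold and 4.33-fold. Prl3a1 of the prolactin family rose 5.37-fold, the vomeronasal receptor Vmn2r79 5.32-fold and Elobl 4.70-fold. These 5 genes belong to families with similar copies, and reads shared with a relative cannot be excluded for them. Tnni3k, a kinase of heart muscle, rose 4.98-fold, Ctxn1 4.16-fold, Nrep 4.13-fold, the nucleic acid sensor Zbp1 3.68-fold and the complement regulator C4bp 3.54-fold.

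Among the falls that the rule takes, Cxcl13, a chemokine that attracts B cells, fell to 0.102 of its Control level, from 473.9 ± 27.2 to 48.5 ± 7.41 (SD, n = 3), a log2 fold change of -3.27 with a standard error of 0.125. The small leucine-rich proteoglycans Fmod, which binds collagen, and Ogn fell to 0.155 and 0.281 of their Control levels. Ogn was abundant in the Control cultures at 1366 ± 31.3. Angptl7 fell to 0.171, Fam107a to 0.188, the receptor Gpr182 to 0.246, the copper transporter Atp7a to 0.25 and the matrix protein Spon2 to 0.267. Abat, which degrades GABA, fell from 1085 ± 52.3 to 284.4 ± 6.43, and the proprotein convertase Pcsk5 from 356.6 ± 9.96 to 95.6 ± 3.51. The potassium channel gene Kcna5 fell to 0.242, with a wider spread in the Control libraries (116.1 ± 43.8).

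Contractile smooth muscle genes were mostly higher: of 21 tested members, 16 rose and 5 fell. Acta2 rose from 58253 ± 107 to 96836 ± 420 (SD, n = 3), the enteric actin Actg2 rose 2.25-fold and tropomyosin Tpm1 1.5-fold. Vcl, which encodes the adhesion protein vinculin, moved the other way and fell to 0.491. Camera placed the list above the other listed genes (adjusted p = 0.0194; adjusted p = 0.355 with an estimated correlation).

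The matrix list was divided, with 16 of 28 members higher and 12 lower (camera adjusted p = 0.237). Loxl1 rose from 9216 ± 110 to 17104 ± 286 (SD, n = 3), the fibrillar collagen gene Col5a2 1.69-fold, Mgp, an inhibitor of calcification, 1.41-fold, and Fbln2 1.37-fold. With each library scaled to its total over the listed genes, 12 matrix genes were higher and 14 lower. After the trend on transcript length and GC content was removed, 22 were higher and 4 lower, and camera placed the list higher (adjusted p = 7.94e-06), but the rise of Mgp shrank from a log2 fold change of 0.49 to 0.07. An estimated correlation was not tried after that removal, and without the removal it gave the list a camera adjusted p of 0.601. Among matrix proteases and inhibitors, 8 of 19 rose and 11 fell (camera adjusted p = 0.547); the median log2 fold change was -0.22, the mean 0.13 and the camera direction downward. Timp1 rose 1.66-fold, from 15970 ± 396 to 26553 ± 153, while the metalloprotease inhibitor Timp2 fell to 0.711 and the aggrecanase Adamts5 to 0.683.

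TGF-beta response genes rose in 13 of 18 cases and fell in 5 (camera adjusted p = 0.0986). The growth factor binding protein Ltbp2 rose 1.56-fold, Pmepa1 1.63-fold and the matrix protein Tgfbi 1.45-fold. With the length and GC trend removed, 13 were higher and 3 lower and camera placed the list higher (adjusted p = 0.00296). Here too an estimated correlation was tried only without the removal, where the camera adjusted p was 0.411.

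In glycolysis, 16 of 17 members rose and 1 fell (camera adjusted p = 1.16e-05; adjusted p = 0.191 with an estimated correlation). Enolase Eno1 rose from 23367 ± 76.3 to 40007 ± 286 (SD, n = 3), triose phosphate isomerase Tpi1 rose 1.76-fold and phosphoglycerate kinase Pgk1 1.57-fold. The lactate exporter Slc16a3 rose 3.21-fold. Hypoxia response genes gave no call (camera adjusted p = 0.668), with 9 of 13 higher and 4 lower: Fam162a rose 1.49-fold and Egln3 1.70-fold, while the vasodilator peptide gene Adm fell to 0.636 and the mitophagy receptor Bnip3l to 0.769.

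NRF2 antioxidant genes were higher in 15 of 19 cases and lower in 4 (camera adjusted p = 9.81e-04; adjusted p = 0.248 with an estimated correlation). Taldo1 of the pentose phosphate pathway rose 3.31-fold, the haem-degrading enzyme Hmox1 1.67-fold, biliverdin reductase Blvrb 1.82-fold and ferritin heavy chain Fth1 1.30-fold. Of 32 nuclear-encoded oxidative phosphorylation genes, 29 rose and 3 fell (camera adjusted p = 1.71e-04; adjusted p = 0.251 with an estimated correlation), with Sdhb at 1.46-fold, Ndufa9 at 1.35-fold and Uqcrq at 1.27-fold. Removal of the trend on transcript length and GC content left 14 higher and 13 lower and ended the call (adjusted p = 0.959), moving the list's median log2 fold change from 0.26 to -0.05. The listed genes of the mitochondrial genome took 1.93% ± 0.031 of listed reads in Control and 1.42% ± 0.023 in siSirt6 (SD, n = 3). Of 9 tested, 6 fell and the other 3 did not pass. They include ribosomal RNA and transfer RNA genes. Other mitochondrial genes lie outside the tables, so these shares do not describe the mitochondrial genome as a whole.

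Genes of the translation machinery rose together. All 50 ribosomal protein genes tested were higher, with log2 fold changes from 0.22 to 0.73 (camera adjusted p = 1.32e-20; adjusted p = 0.251 with an estimated correlation). Rpsa rose 1.52-fold, Rplp0 1.48-fold, Rplp1 1.51-fold and Rpl6 1.66-fold. Together, the share of ribosomal protein genes in listed reads went from 5.91% ± 0.090 to 7.78% ± 0.093 (SD, n = 3). Many of these genes have processed pseudogenes that could take part of their reads. All 25 genes of ribosome biogenesis and MYC rose (camera adjusted p = 1.77e-07; adjusted p = 0.191 with an estimated correlation), among them the nucleolar proteins Mybbp1a at 1.79-fold, Ncl at 1.48-fold and Npm1 at 1.36-fold, and Odc1, which starts polyamine synthesis, at 1.53-fold. With the length and GC trend removed, 41 ribosomal protein genes were higher and 3 lower, and 24 of the biogenesis genes were higher. The median log2 fold change of the ribosomal protein list went from 0.50 to 0.17 on that removal, and Rplp1 went from 0.59 to 0.04.

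All 27 tested genes of the type I interferon response were higher (camera adjusted p = 9.39e-06; adjusted p = 0.164 with an estimated correlation). Bst2, which tethers budding viruses, rose 2.56-fold from 2012 ± 28.4 to 5144 ± 260 (SD, n = 3). The ubiquitin-like Isg15 rose 1.92-fold, Ifit3 2.21-fold and Zbp1 3.68-fold. NF-kB and inflammatory genes were higher in 11 of 14 cases and lower in 3 (camera adjusted p = 0.237). In that list Ccl7, which attracts monocytes, rose 2.93-fold and Csf1 1.19-fold beside Cxcl5, while Vcam1 fell from 7123 ± 109 to 3042 ± 67.8. Senescence-associated secreted factors were higher in 17 of 24 cases and lower in 7 (camera adjusted p = 0.0876), with Mmp3 up 1.53-fold beside Timp1, and Igfbp3 down to 0.509.

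Mitotic genes fell. All 22 tested members of the G2/M list were lower, with log2 fold changes from -0.81 to -0.15 (camera adjusted p = 1.71e-04; adjusted p = 0.164 with an estimated correlation). The mitotic kinesin Kif20a fell from 951.3 ± 15.1 to 598.9 ± 20.6 (SD, n = 3), Prc1, which organises the spindle midzone, fell to 0.671, topoisomerase Top2a to 0.779 and cyclin Ccna2 to 0.71. In the G1/S and S phase list, 4 of 13 genes rose and 9 fell (camera adjusted p = 0.408). The ribonucleotide reductase subunits went apart there, with Rrm1 at 1.16-fold and Rrm2 at 0.842 of Control. Cyclin Ccne2 fell to 0.621 and Uhrf1, which maintains DNA methylation, to 0.791.

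Endothelial markers were higher in all 10 tested cases (camera adjusted p = 0.0157; adjusted p = 0.251 with an estimated correlation, and 0.0716 among genes with a mean of at least 5 CPM of listed values). Kdr rose from 97.2 ± 10.3 to 288.8 ± 36.2 (SD, n = 3), VE-cadherin Cdh5 2.28-fold, the tight junction gene Cldn5 5.98-fold and Emcn 1.39-fold. Cldn5 was low in Control, going from 12.3 ± 5.38 to 73.7 ± 22.6. All 10 had a Control mean of at least 10, and the highest was 617.4, for Emcn. Markers of adventitial fibroblasts were divided, 5 of 10 higher and 5 lower (camera adjusted p = 0.782): Scara5 fell to 0.331 and Gsn, at a Control mean of 72100, to 0.797, while Ly6a rose 1.24-fold and Dpt 1.64-fold. With the length and GC trend removed, 2 fibroblast markers were higher and 6 lower, and the log2 fold changes of Ly6a, C1qb and Lyz2 were -0.05, -0.08 and -0.17, and that of Lyz2 was -0.01 under listed totals. Of 3 tested markers of macrophages and leukocytes, C1qb rose 1.26-fold, Lyz2 1.08-fold and Cd68 1.27-fold, with adjusted p between 0.0557 and 0.0744 over all annotated genes. The call of C1qb was lost under listed totals (log2 0.21, adjusted p = 0.082) and that of Lyz2 with DESeq2 on 5 libraries (0.12, adjusted p = 0.0516). The call of Cd68 was lost in 6 alternatives, among them with the length and GC trend removed (log2 0.02, adjusted p = 0.862), without Control replicate 2 (0.27, adjusted p = 0.0728) and without siSirt6 replicate 1 (0.31, adjusted p = 0.0522).

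**Figure D2:**
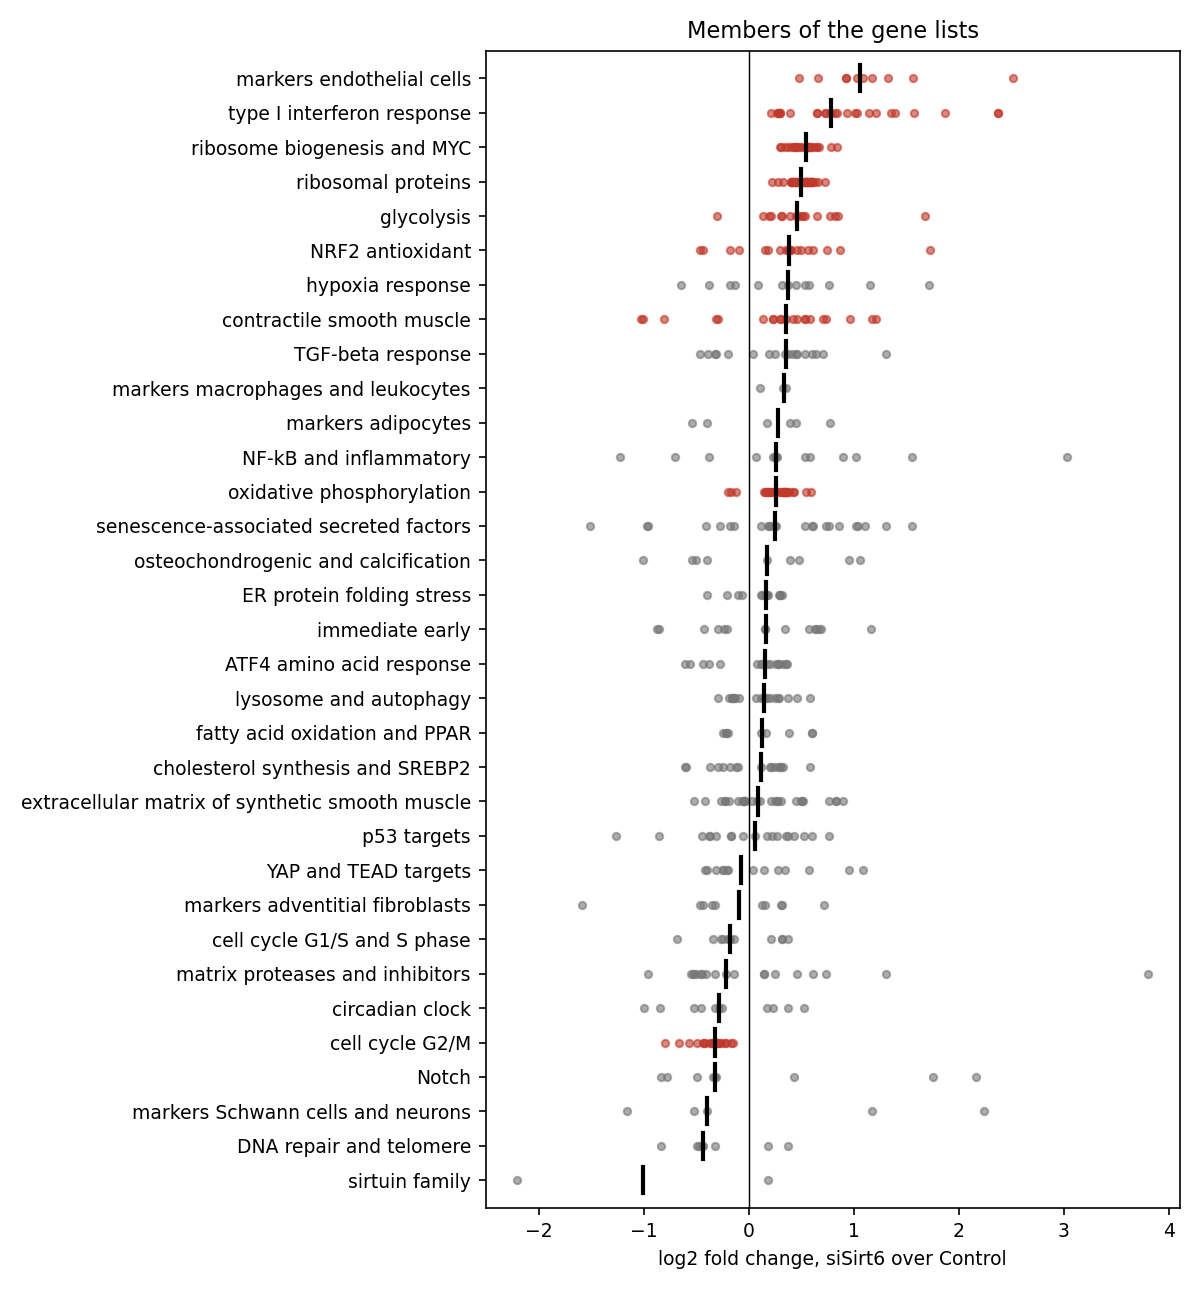
Log2 fold changes of siSirt6 over Control (x axis) of the tested members (points) of 33 gene lists (y axis), with each list's median as a bar and the 9 lists called by camera in red. Of the called lists 8 lie to the right, with medians up to 1.06 for endothelial markers, and the G2/M list lies to the left at -0.32.

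Short genes were higher and long genes lower in siSirt6. Among the fifth of genes with the shortest transcripts (67 to 1799 nt) 82.6% were higher, and among the fifth with the longest (5444 to 123179 nt) 20.8% were. Across genes, which are not independent replicates, Spearman's rho of log2 fold change was -0.43 with transcript length and 0.21 with GC content. With this trend removed, 2676 genes were higher and 2631 lower, and 368 calls took the opposite direction. Of 126 list genes taken by the naming rule, 30 kept at most 0.5 of their log2 fold change, among them Timp1 (0.73 to 0.33), Adamts5 (-0.55 to -0.21), Fam162a (0.58 to 0.17), Rplp0 (0.57 to 0.27) and Top2a (-0.36 to -0.11).

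**Figure D3:**
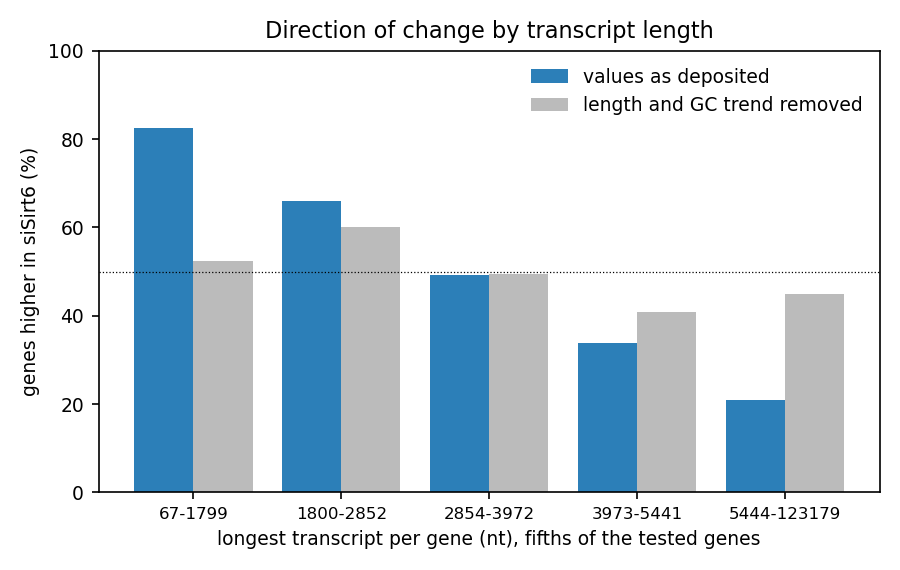
Percentage of tested genes higher in siSirt6 (y axis) in 5 equal groups by the longest annotated transcript in nt (x axis), for deposited values and after each library's trend on length and GC content was removed. The share falls from 82.6% to 20.8% with the deposited values and lies between 40.8% and 60% after removal.

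For all 33 lists, the counts adjusted over the list alone were identical to those given, which the near absence of unchanged genes left little room to alter. With p adjusted over all annotated genes, 27 of 27 interferon, 22 of 22 G2/M and 49 of 50 ribosomal protein genes passed. So did 15 of 19 p53 targets, 18 of 21 lysosome and autophagy genes, and 12 of 14 YAP and TEAD targets, 5 higher and 7 lower. All such counts cover tested members only, and members outside the tables were not analysed here. Tested members were 8 of 36 for DNA repair, 13 of 30 for G1/S and S phase and 22 of 29 for G2/M. They were 14 of 30 for NF-kB, 9 of 25 for osteochondrogenic genes and 3 of 16 for macrophages and leukocytes. For contractile genes they were 21 of 27, and for ribosomal proteins 50 of 51. The tables held almost only genes that differ, so the counts do not estimate how much of the transcriptome changed, and with p adjusted over all 55536 annotated genes 3297 genes were higher and 3188 lower. None of the 9 list calls held with an estimated correlation. For the interferon and G2/M lists the estimates were -0.0069 and -0.0298, below the preset 0.01. Members that vary together therefore do not account for the loss of those calls. Camera compared each list only with other genes in the tables.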

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

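The scaling by TMM, pseudocounts of 0.5 and 5, removal of the length and GC trend, edgeR on 5 libraries and adjustment over all annotated genes were chosen after seeing the data. DESeq2 and limma-voom were planned, but their limit to the recovered reads of 5 libraries followed from the deposited values. Higher and lower counts stayed within 1.5 times of 3624 and 3542 under every alternative; the lowest were 2676 and 2631, with the length and GC trend removed, where 4936 of 7166 calls kept their direction and 368 reversed. The count past 2-fold was 207 in place of 554 with a filter of mean 5 CPM, which removes low genes with large folds. DESeq2 on 5 libraries called 3186 higher and 3122 lower, and edgeR 3546 and 3469. Listed totals moved the median log2 fold change by -0.119, from 0.085 to -0.034, gave 2710 higher and 3567 lower (43.2% of calls higher against 50.6%) and reversed 23 calls. Without 1 library, 3491 to 3577 genes were higher, 3410 to 3473 lower and 498 to 527 past 2-fold, and Sirt6 lay between -2.31 and -2.06. Replicate numbers did not pair the samples (correlations of deviations -0.019, 0.027 and -0.001); with the replicate block 3629 genes were higher, 3540 lower and 554 past 2-fold, and Sirt6 stayed at -2.21. Of 146 genes that the naming rule takes besides Sirt6, 5 reversed with the trend removed: Sirt2 (0.00), Clock (0.11), C1qb (-0.08), Lyz2 (-0.17) and Ly6a (-0.05), and Lyz2 reversed under listed totals (-0.01). Brca1, Wrn and Rora lost their calls with the trend removed. Cd68 lost its call in 6 alternatives, among them without Control replicate 2 and without siSirt6 replicate 1; C1qb lost its call under listed totals (0.21) and Lyz2 with DESeq2 (0.12). The oxidative phosphorylation median reversed with the trend removed (-0.05). By fry, matrix proteases (median -0.22) and YAP and TEAD targets (median -0.08) pointed upward with calls, and 20 other lists gained a call. Fry asks only whether a list's own genes differ, and just 13 of the 7179 tested had an unadjusted limma p of 0.05 or more. Calls by fry were therefore nearly fixed by the selection of genes, and nothing is drawn from them. The causes of other reversals were not tested.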

Other observations

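Notch genes moved in opposite directions: 3 of 9 rose and 6 fell (camera adjusted p = 0.349), with a median log2 fold change of -0.32 and a mean of 0.14. The receptor Notch3 fell from 2515 ± 33.2 to 1464 ± 21.0 (SD, n = 3), its ligand Jag1 fell to 0.558 and the transcription factor Rbpj to 0.708, while the effector Heyl rose 3.37-fold. Immediate early genes were higher in 9 of 15 cases and lower in 6 (camera adjusted p = 0.741): Ier3 rose 2.24-fold, Junb 1.49-fold and Ier5 1.55-fold, and the ERK phosphatase Dusp6 fell to 0.544. YAP and TEAD targets were 7 higher and 7 lower (camera adjusted p = 0.911), pointing downward with a median of -0.08 and a mean of 0.10. They were 4 higher and 8 lower under listed totals. With the length and GC trend removed they were 4 higher and 3 lower, pointing upward with a median of 0.04. The receptor kinase Axl rose 1.93-fold and Ankrd1 2.13-fold, Myof fell to 0.746 and Amotl2 to 0.758. Osteochondrogenic genes were 5 higher and 4 lower (camera adjusted p = 0.668), with Spp1 up 1.31-fold, the cartilage collagen gene Col2a1 up 1.94-fold, the phosphate transporter Slc20a1 up 1.39-fold and Bmp4 down to 0.703. Among p53 targets 10 of 19 rose and 9 fell (camera adjusted p = 0.808, pointing upward; median 0.06, mean -0.02): Trp53inp1 fell to 0.414, while the cell cycle inhibitor Cdkn1a rose 1.27-fold, Ei24 1.34-fold and Gdf15 1.69-fold. Of 36 members of the DNA repair list 8 were tested, of which 2 rose and 6 fell (camera adjusted p = 0.501). Parp1 rose 1.30-fold, the damage kinase Atm fell to 0.559, Brca1 to 0.718 and Wrn to 0.732. With the length and GC trend removed, p53 targets were 9 higher and 9 lower, DNA repair genes were 1 higher and 3 lower, and the calls of Brca1 and Wrn ended. Under listed totals alone, p53 targets were 8 higher and 10 lower.

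Lipid and stress lists gave no call. Cholesterol synthesis genes were 9 higher and 8 lower (camera adjusted p = 0.911, pointing downward; median 0.11, mean 0.00), with Hmgcs1 at 0.773, Idi1 at 0.657 and Mvk at 1.25-fold; fatty acid oxidation genes were 5 higher and 4 lower (camera adjusted p = 0.824), with Plin2 at 1.30-fold, Fabp3 at 1.51-fold and Angptl4 at 1.52-fold. Under listed totals these lists turned to 7 higher and 8 lower, and 3 higher and 4 lower. With the length and GC trend removed they were 7 higher and 5 lower, and 4 higher and 2 lower. ER protein folding genes were 10 higher and 4 lower (camera adjusted p = 0.193), and 5 higher and 5 lower with the length and GC trend removed, with the chaperone Hspa5 at 1.22-fold, Calr at 1.24-fold, Hyou1 at 1.23-fold and Pdia3 at 1.13-fold. ATF4 targets were 11 higher and 5 lower (camera adjusted p = 0.408), with Phgdh at 1.27-fold, Atf4 at 1.29-fold, Ddit4 at 0.676 and Slc3a2 at 1.22-fold. With the length and GC trend removed, ATF4 targets were 8 higher and 5 lower, and the log2 fold changes of Phgdh and Atf4 shrank from 0.35 to 0.10 and from 0.36 to 0.14. Others that shrank to at most 0.5 of their value were Fabp3 (0.60 to 0.16), Ctsd (0.24 to 0.04), Adipoq (0.44 to 0.16), Cfd (0.77 to 0.34), Cdkn1a (0.35 to 0.15), Plin2 (0.38 to 0.19), Mvk (0.32 to 0.15), Rbpj (-0.50 to -0.24) and Myof (-0.42 to -0.14). Lysosome and autophagy genes were 13 higher and 8 lower (camera adjusted p = 0.349), and 7 higher and 8 lower under listed totals, with Ctsl at 1.37-fold, Ctsd at 1.19-fold, Lamp2 at 0.816 and Sqstm1 at 1.21-fold. Clock genes were 4 higher and 7 lower (camera adjusted p = 0.741), and 3 higher and 2 lower with the length and GC trend removed, with Nfil3 at 1.44-fold, Bhlhe40 at 1.29-fold, Clock at 0.835 and Rora at 0.693; on that removal the call of Rora ended and Clock was at 0.11 on the log2 scale. Adipocyte markers were 4 higher and 2 lower (camera adjusted p = 0.749), with Cfd at 1.71-fold, Pparg at 0.685, Adipoq at 1.36-fold and Plin1 at 0.756. Markers of Schwann cells and neurons were 2 higher and 3 lower (camera adjusted p = 0.988, pointing upward; median -0.40, mean 0.26), with Tubb3 at 2.26-fold, S100b at 0.444 and Stmn2 at 4.85-fold. Stmn2 was low, going from 10.4 ± 4.77 in Control to 50.2 ± 15.6 in siSirt6. Chosen after their values were seen, Tagln, a usual smooth muscle marker, had a Control mean of 178.7 ± 32.3 beside 58253 for Acta2, Mmp9 rose from 1.94 to 40.7 and the Notch ligand Dll4 from 11.7 to 56.7.

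The patterns weighed next, and the removal of the length and GC trend, were chosen after the results were seen. The real split gave 7166 genes past the threshold in 1 of the 10 splits of the 6 libraries into 3 and 3, and the highest of the other splits gave 0; so few splits cannot give a share under 0.05, and the genes had been selected on the real split.

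Higher levels of short genes and lower levels of long genes in siSirt6 may come from RNA handling or library preparation as well as from the cells. Among the listed genes, length effects that vary from library to library are argued against. The slopes within a group spanned 7.6% of the slope between the groups, which was -0.214 in log2 per doubling of length. These genes had been selected on the real split, which may lower that percentage, so the result does not reach beyond them. Removal of the trend left part of the rise of ribosomal protein genes, whose median went from 0.50 to 0.17 (0.025). It left most of that of ribosome biogenesis genes, which went from 0.54 to 0.48 (0.045). The rise of oxidative phosphorylation genes went with the trend: their median went from 0.26 to -0.05 (0.037) on removal. In brackets are standard errors of the mean over member genes, which are not independent replicates. Lengths were those of the longest annotated transcript, which need not be the one expressed. Removal can therefore take too much or too little, and it does not decide whether the trend was the whole cause. A length effect shared by the libraries of a group, and an effect of Sirt6 loss on long genes, were not tested and stay open.

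The interferon response was not removed with the length and GC trend, with a median log2 fold change of 0.69 against 0.78 before. The standard error of the mean over its member genes, which are not independent replicates, was 0.124. A response to introduced small RNA, rather than to the loss of Sirt6, is a candidate explanation that 1 siRNA condition leaves untested.

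Endothelial markers may rise because the siSirt6 cultures held more endothelial cells, or because the cells themselves expressed them more. A second endothelial list of 41 genes, fixed before its values were looked up, was used as the test: 66.7% of its 18 tested genes were higher, with a median log2 fold change of 0.64. The percentage lay between cut-offs set beforehand for a larger share of endothelial cells and for its absence. The median met the cut-off for a larger share. The tested genes came from tables of selected genes, which leave out other members of the list. The test therefore cannot decide, and the explanations cannot be told apart. Plvap rose from 175.6 to 398.8 and the abundant Flt1 from 1998 to 2557, but 6 genes fell, among them Lyve1 from 550.7 to 361.7 and Calcrl from 432.8 to 264.3. These examples were chosen after their values were seen. A change of endothelial genes within the smooth muscle cells was not tested.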
